A study of Mus musculus with 96 samples.

How the data were processed

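RNA was sequenced from mouse liver, liver tumours, metastases and liver organoids (3D cultures of liver cells) in 96 libraries that fall into 14 kinds of group by tissue, tumour model and site. Per the labels' protocols, tissue was dissected, organoids were cultured without treatment, total RNA was isolated with a Qiagen RNeasy Micro kit and libraries were stranded. The labels do not expand the names PPTR, PNR, LCS, HBS and F2, which are used here as given. A tumour called driven by LCS, HBS1 or HBS1_F2 carries the name of an organoid line in its label, and the labels do not say how it was made.

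The deposited files hold counts, that is, the number of sequencing reads given to each of 34591 gene symbols in each library, followed by 5 entries for reads given to no gene. Per the submitters' processing notes, BWA, STAR and HTSeq were used with the mouse build mm9, and their versions, order and settings and the annotation release are not given in the sources used here. The deposited values were whole numbers with a different sum in each library, and the authors gave no normalised values. Genes are named by the symbols of the files. Their chromosome positions on mm9 are not given in the sources used here. The 5 entries were used only to describe the libraries. Reads may be shared between nearly identical genes, so values of single members of the Mup, Cyp2c, Sult2a, Sprr2a, Hba and Hbb families are uncertain. 6 features that lie in ribosomal repeats were kept, and their share of each library is given as a sign of ribosomal RNA.

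Each comparison was fitted with edgeR 4.0.16 in R 4.3.3 on its own groups, with 2 exceptions. LCS-driven primary tumours and lung and peritoneal metastases shared a fit. HBS1_F2-driven metastases and primary tumours were fitted together with HBS1-driven primary tumours (n = 2). Genes were kept by filterByExpr with a minimum count of 10, a minimum total of 15, a large group size of 10 and a proportion of 0.7. Libraries were scaled by TMM, a quasi-likelihood model was fitted across all genes, and p-values were adjusted by Benjamini and Hochberg over the genes tested. A gene was called higher or lower at an adjusted p under 0.05, and "rose" and "fell" are used of called genes only. Fold changes are fitted log2 values followed by ± and their standard error. Levels are mean CPM, that is, counts as a share of the library total on the usual CPM scale, adjusted by TMM, with the standard deviation (SD) over libraries where one is given. In the 4 comparisons that involve LCS or HBS organoids against another group, the libraries of one line were summed, so that a line is the replicate there. Each normal organoid library is its own replicate, since the labels name no line for it. The labels do not say which libraries come from separate animals, so p-values measure the spread between libraries.

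15 comparisons, their tests, the gene lists and the naming rule were fixed before the data were examined. The rule names Trp53, Notch1 and Prom1, among others, in every comparison. It adds the genes with the largest fitted changes among the called ones with a mean of at least 10 CPM in the higher group and no predicted or clone name. These are 10 each way in 7 main comparisons, 5 each way in the others and 3 each way in the test of a difference between comparisons. From each list it takes up to 4 called members with a mean of at least 5 CPM. Some genes under this rule are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

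The 30 gene lists cover hepatocytes, bile acid synthesis and transport, biliary epithelium, hepatoblast and fetal liver, stem and progenitor markers, proliferation, the Notch pathway, p53 targets, fatty acid synthesis, cholesterol synthesis, beta-catenin targets and mesenchymal transition. Others cover fibroblasts and stellate cells, endothelium, macrophages and Kupffer cells, T and NK cells, B and plasma cells, neutrophils, erythroid cells, lung epithelium, intestinal epithelium, pancreatic acini, mesothelium, adipocytes and skeletal muscle. The last 5 cover hypoxia and glycolysis, immediate early genes, the interferon response, matrix proteases and invasion, and mitochondrially encoded genes. 3 listed genes matched no symbol. Each list was tested against the other genes by camera in limma 3.58.1 on log2 CPM with a prior count of 2 and the correlation between genes estimated from the data. The preset correlation of 0.01 was an alternative. P-values of lists were adjusted over the lists of a comparison. Members called are also counted with p-values adjusted over the list alone. Where a list count is printed without this second count, the second equals the count over all genes tested. Lists with fewer than 3 genes tested had no list test.

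A ratio against a group in which a gene has 0 counts is computed from the floor of 3 counts over the whole group and written as a lower bound. Against a group with 1 to 3 counts the ratio of pooled CPM is given with its 95% exact interval. These intervals and floors cover counting error only.

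The labels give no batch or date. The library identifiers fall into 9 blocks by their leading number, and these blocks stand in for batches. Alternatives planned in advance were DESeq2 size factors, the DESeq2 1.42.0 test, no filter on low counts, single blocks, the block as a covariate, every library as a replicate, leaving out each replicate of a group of 5 or fewer, leaving out PPTR tumours with another sample-type code in their identifier, leaving out the intrahepatic metastasis, pooling HBS1- and HBS1_F2-driven primary tumours, HBS1_F2 as another HBS line, and the preset correlation for lists. Alternatives chosen after seeing the data were protein-coding features only (20695 symbols), sex or the ribosomal-repeat share as a covariate, and leaving out or summing libraries that stood apart or matched closely. Up to 100 other splits of the same libraries were drawn per comparison with the seed 2024.

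The test was tried on simulated data with the group sizes and depths of 3 comparisons. With 11 against 6 libraries it called 51% of genes changed 2-fold and 90% of those changed 4-fold. With 5 lines against 6 libraries the shares were 16% and 66%, and with 3 against 10 they were 29% and 73%. It called 12 of 14761, 5 of 15180 and 7 of 17981 unchanged genes, which were 7.7%, 5.5% and 6.1% of its calls. Beside 1 changed list, 100 genes were changed by each fold size. The shares called need not hold where many more genes differ. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. HBS1-driven primary tumours (n = 2) were a further group in the fit of HBS1_F2-driven metastases against primary tumours. They add there to the filter, the scaling and the estimate of the spread. Beyond that they were used only in an alternative and as described values.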

Results

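The series compares normal liver, liver organoids and primary liver tumours of mice, and its title concerns organoids derived from primary tumours and metastasis. The 96 libraries comprise 6 of normal liver, 11 of PPTR primary tumours, 5 of PPTR metastases, 9 of PNR primary tumours, 10 of LCS-driven primary tumours, and 5 and 3 of LCS-driven lung and peritoneal metastases. There are 6 libraries of normal liver organoids, 19 of LCS organoids from 5 lines, 11 of HBS organoids from 6 lines and 4 of HBS1_F2 organoids. HBS1-driven and HBS1_F2-driven primary tumours have 2 libraries each, and 3 come from HBS1_F2-driven peritoneal metastases. Gene counts per library ran from 4.4 M to 87.1 M with a median of 29.5 M, and 17065 to 29869 genes had at least 1 count.

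Normal livers had a ribosomal-repeat share of 10.7% to 25.8% and 20.2% to 42.8% of reads not aligned. Single libraries of other groups reached such values, such as LCS-driven peritoneal metastasis 1 with 34.9% and 36.7% and LCS4 organoid 2 with 11.6% and 20.6%. PNR tumours had 0.925% to 2.12% and PPTR primary tumours 0.21% to 18.3% of counts in ribosomal repeats. RNaseP_nuc, the RNA of nuclear RNase P, was at 20 CPM or more in 5 of 6 normal livers, 11 of 11 PPTR primary tumours and 19 of 19 LCS organoids. It reached that level in 0 of 6 normal organoids, 1 of 11 HBS organoids and 3 of 9 PNR tumours. By Xist and the Y-linked gene Ddx3y, 3 normal livers expressed Xist alone and 3 Ddx3y alone. Among normal organoids 3 libraries expressed Ddx3y alone and 3 expressed both, whereas 15 LCS organoid libraries expressed Xist alone and 4, all of LCS5, Ddx3y alone, and 9 HBS organoid libraries Xist alone and 2 Ddx3y alone. Sex therefore differs between these groups, and no organoid comparison was adjusted for it. All 10 LCS-driven primary tumours expressed Xist alone. Of PPTR primary tumours 8 expressed Xist alone, 2 Ddx3y alone and 1 both. Of PNR tumours 5 expressed Xist alone and 4 Ddx3y alone.

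**Figure D1:**
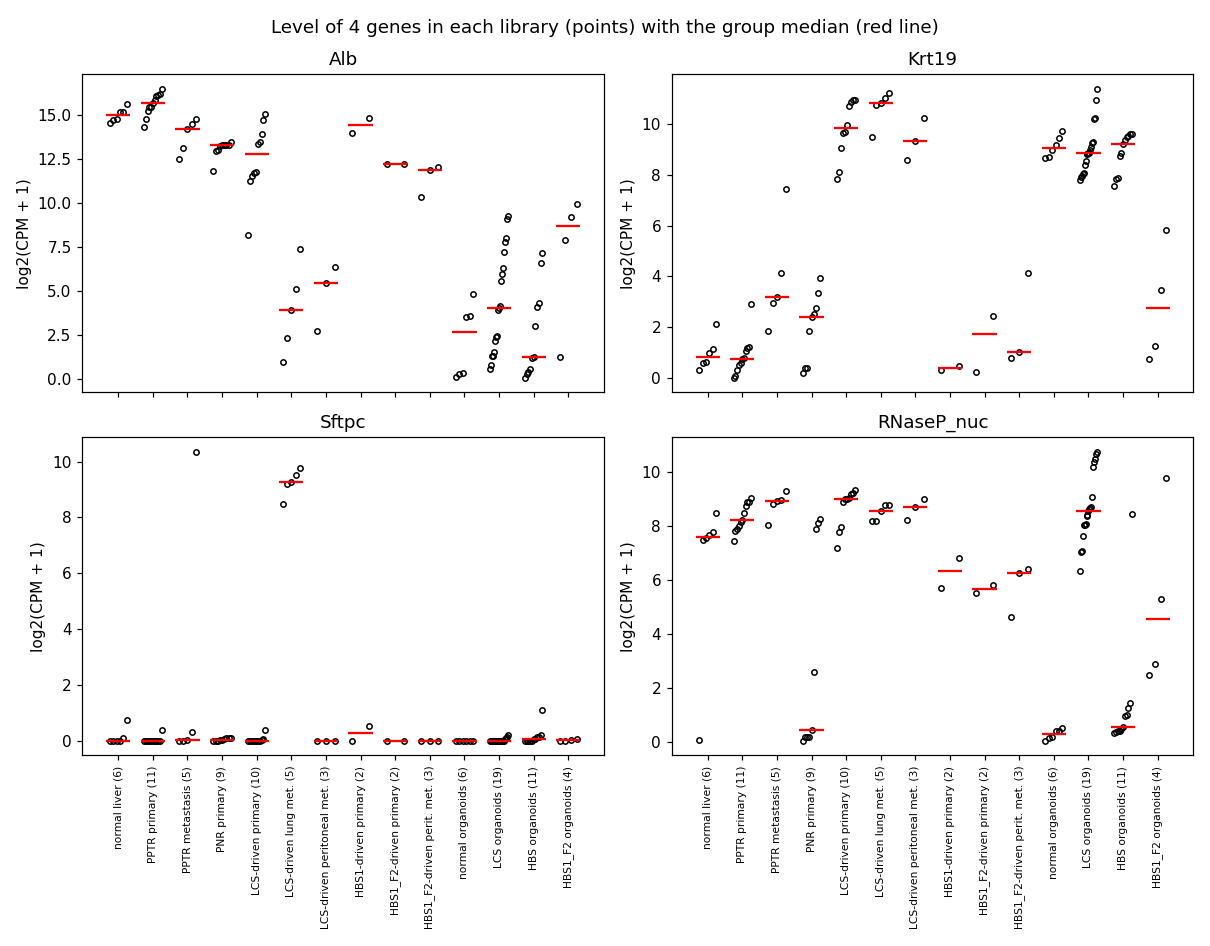
Level of albumin (Alb), the biliary keratin Krt19, Sftpc (lung surfactant protein C) and RNaseP_nuc as log2(CPM + 1) on the vertical axes, in each of the 96 libraries (points) by group (horizontal axis, number of libraries in brackets), with group medians as red lines. Sftpc was at 353 CPM or more in the 5 LCS-driven lung metastases and at most 0.319 CPM in the 10 LCS-driven primary tumours.

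**Figure D2:**
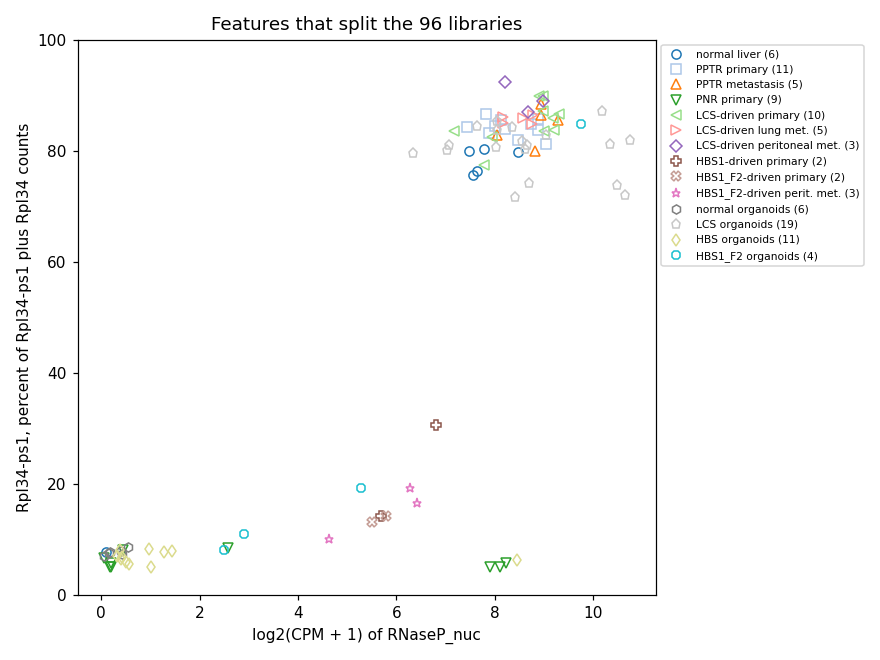
Share of Rpl34-ps1 in the sum of Rpl34-ps1 and Rpl34 counts (percent, vertical axis) against log2(CPM + 1) of RNaseP_nuc (horizontal axis) in the 96 libraries, with a symbol per group. Normal organoids reach at most 8.7%, LCS organoids start at 71.7%, and 9 libraries lie between these values.

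PPTR primary tumours (n = 11) were set against normal liver (n = 6). Cidec and Cidea, which coat lipid droplets, rose by 6.73 ± 0.65 and 8.92 ± 0.98. Cidec went from 0.809 to 84.8 CPM (SD 52.8). The receptor kinase Ephb2 rose by 6.74 ± 0.6, the sodium phosphate transporter Slc34a2 by 6.8 ± 1.11 and the secreted protein Scube3 by 7.05 ± 0.95. Tmc5, a transmembrane channel-like protein, averaged 15.3 CPM (SD 9.25) in tumours and was 1560 times its level in liver (95% interval 280 to 61700). Some large means came from 1 tumour. H19, an imprinted noncoding RNA (8.88 ± 2.19, adjusted p = 0.00518), was at 3090 CPM in tumour 3 and at most 200 CPM in the others. Apelin (Apln, 7.92 ± 1.53) reached 180 CPM in tumour 9 against at most 9.87 in the others, and placental growth factor (Pgf, 7.45 ± 1.85) reached 101 CPM there against at most 31.6. Psapl1, at least 663-fold higher than in liver, was at 122 CPM in tumour 7 and at most 10.2 in the others.

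Igfbp2, an IGF-binding protein, fell by 6.79 ± 0.78 from 533 to 4.83 CPM. The cytochromes Cyp2c37 (-6.32 ± 1.02), Cyp2c50 (-5.4 ± 0.99) and Cyp2c54 (-5.23 ± 1.12) fell with the sulfotransferases Sult2a3 (-6.61 ± 1.44), Sult2a1 (-5.47 ± 1.42) and Sult3a1 (-5.71 ± 1.19). These sulfotransferases were uneven across livers, with means there of 27.2 CPM (SD 62.4), 175 CPM (SD 253) and 120 CPM (SD 184), in that order. The uridine phosphorylase Upp2 fell by 5.34 ± 0.72. The organic anion transporters Slc22a26 (-5.7 ± 0.6) and Slco1a1 (-5.56 ± 1.35) fell too. Of 22 hepatocyte genes 14 fell and 0 rose, also when adjusted over the list alone. They include Cyp2e1 (-4.19 ± 0.88), the gluconeogenic enzyme Pck1 (-3.61 ± 0.59) and Tat (-3.17 ± 0.49), while Alb had 0.19 ± 0.74 (adjusted p = 0.871). Of 14 bile acid genes 10 fell, 11 over the list alone, among them Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-3.91 ± 0.6), and the bile acid importer Slc10a1 (-2.24 ± 0.43). 9 of 14 beta-catenin targets fell, 12 over the list alone, including Oat (-3.74 ± 0.56) and the glutamate transporter Slc1a2 (-4.02 ± 0.76).

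Of the biliary genes 7 of 14 rose, 9 over the list alone, with osteopontin (Spp1) up 4.73 ± 0.71. Hepatoblast genes rose in 7 of 10 and fell in 1, or 2 over the list alone, and Igf2bp3 rose by 5.45 ± 0.91 while the imprinted gene Peg3 fell by 2.64 ± 0.93. Stem and progenitor markers rose in 5 of 11 and fell in 1. Ly6d rose by 5.79 ± 0.58 to 247 CPM. Of 24 proliferation genes 16 rose, 19 over the list alone, with the ribonucleotide reductase subunit Rrm2 up 2.16 ± 0.43. Of 18 p53 targets 7 rose, 8 over the list alone, with the cell cycle inhibitor Cdkn1a up 3.1 ± 0.63, and 6 of 13 Notch pathway genes rose, with the ligand Jag1 up 1.21 ± 0.28. Fatty acid synthesis genes rose in 7 of 15, 10 over the list alone. The desaturase Scd2 rose by 4.74 ± 0.64 and Scd1 by 2.46 ± 0.66. Of 15 matrix protease genes 10 rose, 11 over the list alone, such as lysyl oxidase (Lox, 4.29 ± 0.92), and of 16 fibroblast genes 7 rose, 8 over the list alone, and 1 fell, with collagen Col1a1 up 3.49 ± 0.5. Hypoxia and glycolysis genes rose in 9 of 17, 11 over the list alone, with hexokinase Hk2 up 3.3 ± 0.56. Lung list genes rose in 4 of 6, intestinal in 4 of 5, adipocyte in 4 of 5 and pancreatic in 2 of 2. Keratin 20 (Krt20, 6.3 ± 1.34) and the fatty acid binder Fabp4 (3.94 ± 0.62) are examples. Macrophage genes fell in 4 of 15, with the scavenger receptors Marco (-4.62 ± 1.08) and Cd163 (-4.32 ± 0.61) among them.

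For the remaining lists the members higher and lower were 0 and 2 of 21 for cholesterol synthesis (0 over the list alone), 1 and 2 of 14 for mesenchymal transition, 1 and 4 of 14 for endothelium and 0 and 2 of 14 for T and NK cells. They were 0 and 2 of 9 for B cells (0 and 4 over the list alone), 3 and 2 of 11 for immediate early genes (5 and 3), 1 and 1 of 13 for interferon and 1 and 2 of 9 for mitochondrial genes. No neutrophil gene of 10, erythroid gene of 8, mesothelial gene of 5 or muscle gene of 1 was called. With an estimated correlation the adjusted p was 0.241 for the hepatocyte, bile acid, hepatoblast, stem, beta-catenin, lung, intestinal, adipocyte and matrix lists and higher for the rest, except the pancreatic and muscle lists, which had too few genes for this test. Notch1 (0.06 ± 0.25), Trp53 (0.03 ± 0.25) and the progenitor marker Prom1 (1.37 ± 1.0) were not called. edgeR called 2801 genes higher and 2246 lower of 15305 tested, 1584 and 950 of them by more than 2-fold. Without tumours 10 and 11, whose identifiers carry the sample-type code usual for metastases, the counts were 2431 and 2002. With the ribosomal-repeat share as a covariate the counts were 1560 and 1101. Of the named genes 60 then kept direction and side of the threshold, 43 lost the call, 1 moved and 1 reversed. The mitochondrial gene mt-Nd1 went from 1.0 ± 0.31 to -0.03 with that covariate.

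PNR primary tumours (n = 9) were set against normal liver (n = 6). The fetal growth factor Igf2 rose by 12.96 ± 0.72 from 0.188 to 1720 CPM (SD 763), and H19 by 11.86 ± 0.72 to 2770 CPM (SD 955). Rtl1, an imprinted retrotransposon-like gene, was at least 453-fold higher. The uroplakin Upk3a, a urothelial membrane protein, averaged 370 CPM (SD 304) and was at least 14500-fold higher. Stanniocalcin 1 (Stc1) was at least 667-fold and Trim50 at least 370-fold higher. The steroid enzyme Akr1c18 rose by 10.3 ± 0.71 to 133 CPM (SD 18.4). Ratios were 1670 for the steroid enzyme Hsd3b1 (300 to 66100), 6660 for the lipase relative Pnliprp1 (1200 to 263000) and 1400 for the gastrokine Gkn3 (251 to 55300). All 10 genes with the largest falls encode major urinary proteins. Mup1 had -14.39 ± 1.66 and Mup3 -14.14 ± 1.33, from 2550 to 0.134 CPM.

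Hepatocyte genes fell in 13 of 22 and rose in 1, the same over the list alone. Cyp3a11 (-7.94 ± 0.95) and the urea cycle enzyme Cps1 (-4.01 ± 0.73) fell. Bile acid genes fell in 9 of 14, with Cyp8b1 at -8.36 ± 0.68. Macrophage genes fell in 13 of 15, with the Kupffer cell lectin Clec4f down from 330 to 1.65 CPM (-7.63 ± 0.98). T and NK cell genes fell in 7 of 10, B cell genes in 5 of 7 and endothelial genes in 6 of 14, the last 2 lists with 1 gene higher each. Of 14 beta-catenin targets 10 rose and 0 fell, among them the negative regulator Axin2 (3.25 ± 0.64), Sp5 (3.66 ± 0.96) and the ammonium transporter Rhbg (3.56 ± 0.69). The stem cell marker Lgr5 rose by 3.42 ± 0.82 to 75.8 CPM. Notch pathway genes rose in 8 of 13 and fell in 1. The Notch target Nrarp rose by 5.87 ± 0.59, Heyl by 4.0 ± 0.55 and Hes1 by 2.17 ± 0.25. Proliferation genes rose in 17 of 24, 20 over the list alone, with the replication helicase subunit Mcm6 up 2.6 ± 0.58. Alpha-fetoprotein (Afp), of fetal liver, rose by 7.63 ± 1.99 and ran from 1.02 to 652 CPM across the tumours. Its median there was only 2.2 CPM, with 652 CPM in tumour 9 and 380 CPM in the next highest tumour. Fatty acid synthesis genes fell in 7 of 15 and rose in 1, since Thrsp fell by 5.9 ± 0.86 and Scd2 rose by 5.09 ± 0.27. Mitochondrial genes rose in 7 of 9, with mt-Nd1 up 2.08 ± 0.22.

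Notch1 (1.23 ± 0.21) and Trp53 (1.63 ± 0.25) rose, and Prom1 had 2.35 ± 1.17 (adjusted p = 0.107). Prom1 was at 0.313 to 0.417 CPM in tumours 4 to 6 and at 38.5 to 91.5 CPM in the other 6, and without tumours 4 to 6 it was called (2.92 ± 0.75). No list was called with an estimated correlation, where the smallest adjusted p was 0.588. edgeR called 4304 genes higher and 3454 lower of 15739. No identifier block holds both PNR tumours and normal livers, so group and block cannot be told apart. Their ribosomal-repeat shares do not overlap, and with the share as a covariate 1 gene was higher and 1 lower. The 8 PPTR tumours with a share under that of every PNR tumour had Igf2 at 0.131 to 3.18 CPM, where PNR tumours had 679 to 3270. Some PNR libraries match closely, 2 and 3, 4 to 6, and 7 and 9, with an SD of log2 ratios of 0.19 to 0.31 within these sets. With each set summed (n = 5) the counts were 3608 and 2843.

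PPTR (n = 11) and PNR primary tumours (n = 9) were compared directly. PPTR tumours had the major urinary proteins, with Mup3 at 458 against 0.151 CPM (11.49 ± 1.26) and Mup20 at 356 against 0.39 CPM (9.79 ± 1.01). PNR tumours had the imprinted noncoding RNA Meg3, at 292 CPM (SD 110) against 0.664 CPM (-8.84 ± 0.69). Rtl1 was at least 1730-fold lower in PPTR tumours. Upk3a was 55500 times higher in PNR tumours (19000 to 269000), Pnliprp1 had -10.98 ± 1.06 and the ligase Trim9 -8.5 ± 0.95. All 14 beta-catenin targets were lower in PPTR tumours, adjusted p = 0.813 with an estimated correlation. Slc1a2 had -7.12 ± 1.22, Axin2 -4.64 ± 0.59 and Oat -4.88 ± 0.59, and the marker Lgr5 had -6.63 ± 0.83. Notch pathway genes were lower in 6 and higher in 2 of 13, with Heyl at -4.01 ± 0.32. Fatty acid synthesis genes were higher in 11 of 15, such as Acly, which makes acetyl-CoA for lipids (3.32 ± 0.41). Macrophage genes were higher in 12 of 15, with Clec4f at 5.45 ± 1.08. Fibroblast genes were higher in 11 of 16, T and NK cell genes in 8 of 13 and interferon genes in 8 of 13, 10 over the list alone. Decorin (Dcn) had 2.9 ± 0.41.

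Hepatocyte genes went both ways, 5 higher and 7 lower of 22, with Cyp3a11 at 7.17 ± 0.88 and Cyp2e1 at -3.41 ± 0.83. Mitochondrial genes were lower in 7 of 9, with mt-Cytb at -2.35 ± 0.23. Notch1 (-1.17 ± 0.19) and Trp53 (-1.6 ± 0.18) were lower in PPTR tumours, and Prom1 was not called (-1.0 ± 0.93). Of the hepatoblast genes 3 were higher and 5 lower of 13. Peg3 (-5.06 ± 1.55) and Afp (-3.7 ± 1.18) were lower by edgeR, but had 1.54 and 1.04 by DESeq2. edgeR called 3915 genes higher and 4255 lower of 15645, and 4274 and 7105 without the filter on low counts. The lists all had an adjusted p of 0.813 or more with an estimated correlation. No identifier block holds tumours of both models, so block and model cannot be told apart. The share of Rpl34-ps1 in its sum with Rpl34 was 81.3% to 86.6% in PPTR and 5.08% to 8.48% in PNR tumours. That split and the model cannot be told apart either. The closely matching PNR libraries 2 and 3, 4 to 6, and 7 and 9 were counted here as separate tumours, so the standard errors may be too small.

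LCS organoids (n = 5 lines) were set against normal liver organoids (n = 6). Among secreted liver products, apolipoprotein B (Apob) rose by 7.01 ± 1.37 from 34.7 to 4490 CPM (SD 4700), and fibrinogen beta (Fgb) by 7.79 ± 1.67 to 265 CPM (SD 429). The canalicular export pump Abcc2 rose by 8.38 ± 1.49 to 305 CPM. Higher levels were also found for Mettl7b (10.44 ± 1.57), the serum protein Itih5 (10.06 ± 1.49), the glycosyltransferase B4galnt2 (8.19 ± 1.3), the alcohol dehydrogenase Adh7 (8.02 ± 0.94), the brush border cadherin Cdhr2 (7.59 ± 1.4) and the matrix protein Sparc (7.2 ± 1.6). Sparc was uneven over the LCS lines, with a mean of 38.5 CPM (SD 80). RNaseP_nuc rose by 11.6 ± 0.74 to 731 CPM (SD 470), and was at 20 CPM or more in 19 of 19 LCS and 0 of 6 normal organoid libraries. The share of Rpl34-ps1 in its sum with Rpl34 was 71.7% to 87.1% in LCS and 7.14% to 8.7% in normal organoids. This split of the libraries and the kind of organoid cannot be told apart for the genes called here. Genes that fell include the proton exchanger Slc9a4 (-7.23 ± 1.11), the transcription factors Ebf1 (-6.7 ± 0.98) and Sox17 (-3.79 ± 0.91), the anion transporter Slc26a9 (-4.08 ± 0.81), the lipid flippase Atp10b (-4.58 ± 0.63), the ceramide synthase Lass3 (-4.37 ± 0.45) and AC120136.3 (-5.03 ± 0.62). The carboxylesterase Ces1f (-5.42 ± 1.34), Wdr72 (-4.72 ± 1.06) and osteoprotegerin (Tnfrsf11b, -3.61 ± 0.95) complete the 10 largest falls.

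Interferon genes rose in 8 of 13, 10 over the list alone with 1 lower, adjusted p = 0.261 with an estimated correlation. The antiviral enzyme Oas1a rose by 3.62 ± 0.59 and the regulator Irf7 by 2.14 ± 0.35. Hypoxia and glycolysis genes rose in 7 of 18, 16 over the list alone, adjusted p = 0.71 with an estimated correlation, with the mitophagy protein Bnip3 up 3.65 ± 0.76. Hepatocyte genes rose in 3 of 14, 6 over the list alone, adjusted p = 0.874, with hemopexin (Hpx) up 3.42 ± 0.65. Cholesterol synthesis genes rose in 1 of 21 and in 9 over the list alone, adjusted p = 0.71. Scd1 rose by 3.5 ± 0.63 and the retinal dehydrogenase Aldh1a1 by 3.52 ± 0.68. No proliferation gene of 24 and no Notch pathway gene of 10 was called, beside 3592 genes at an unadjusted p under 0.05 in the whole table and DESeq2 calls of 1399 higher and 994 lower. Notch1 (-0.05 ± 0.3), Prom1 (-3.22 ± 0.98, adjusted p = 0.072) and Trp53 (-0.54 ± 0.3) were not called.

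edgeR called 587 genes higher and 346 lower of 15563. The counts were 286 and 181 without LCS1, 272 and 166 without LCS2, and 933 and 539 without LCS5. Of 38 called genes that were followed, 23 kept their call whichever line was left out. Those that lost it include Tnfrsf11b, Sox17, Ces1f and Wdr72, with an adjusted p of 0.109 for Tnfrsf11b without LCS2.

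Between HBS organoids (n = 6 lines) and normal organoids (n = 6) few genes were called. The sum of line HBS1 includes its library 3, whose sex markers differ from those of the other HBS1 libraries. Mesothelin (Msln), a surface protein of mesothelium and some tumours, fell by 1.85 ± 0.27 from 1370 CPM (SD 472) to 381 CPM (SD 92.6), adjusted p = 0.0247. Lass3 (-3.47 ± 0.43) and the splicing regulator Clasrp (-1.09 ± 0.15) fell, as did the retinol dehydrogenase Rdh10 (-1.19 ± 0.2), from 392 to 172 CPM. Edem2, of protein degradation in the endoplasmic reticulum, fell by 0.95 ± 0.14, and Khnyn (-1.01 ± 0.17), Cuedc1 (-1.46 ± 0.24) and Gdpd5 (-1.43 ± 0.24) fell as well. The rest of the 11 lower genes are Apobr, Pik3r5 and Gm3453. The 1 higher gene, Frem2 of the basement membrane, was chosen after its values were seen, with 7.82 CPM (SD 4.49) against 1.13 CPM (SD 0.344). edgeR called 1 gene higher and 11 lower of 14994, with 1808 at an unadjusted p under 0.05. DESeq2 called 254 and 256, and edgeR with every library as a replicate called 195 and 231.

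Within the lists mesothelium had 1 gene lower of 2, Msln, and no other list had a called member over all genes tested. Over the list alone 2 of 4 neutrophil genes, 2 of 11 matrix protease genes and 1 of 4 bile acid genes were lower. Their adjusted p with an estimated correlation was 0.269, 0.436 and 0.311. Also over the list alone, 1 gene each was lower in the beta-catenin and muscle lists and higher in the fibroblast, endothelial and lung lists. Notch1 (0.32 ± 0.33), Prom1 (-0.1 ± 0.54) and Trp53 (0.53 ± 0.22) were not called.

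LCS organoids (n = 5 lines) had more RNA for Mettl7b (8.88 ± 1.6), the chloride channel regulator Clca6 (8.69 ± 1.66), the liver hormone Fgf21 (8.27 ± 1.46), Tmigd1 (8.23 ± 1.39) and apolipoprotein C2 (Apoc2, 7.95 ± 1.7) than HBS organoids (n = 6 lines). The X-linked genes Xlr3a (-6.56 ± 1.25) and Xlr3b (-4.83 ± 1.2) were lower, with Wdr72 (-5.24 ± 0.65), AC120136.3 (-5.43 ± 0.32) and the potassium channel Kcnh5 (-7.67 ± 1.74). The share of Rpl34-ps1 in its sum with Rpl34 was 71.7% to 87.1% in LCS and 5.06% to 8.39% in HBS organoids. Here too this split and the kind of organoid cannot be told apart. Prom1 was lower, at 46.7 CPM (SD 46.3) against 405 CPM (SD 103), adjusted p = 0.0377. It lost its call in 3 of 5 fits that left out 1 LCS line (adjusted p up to 0.0957, without LCS2). Vimentin (Vim), an intermediate filament of mesenchymal cells, was higher at 96.5 CPM (SD 99.4) against 1.28 CPM. It lost its call in 2 of these 5 fits (adjusted p up to 0.0527, without LCS1). Interferon genes were higher in 8 of 13, 10 over the list alone, adjusted p = 0.168 with an estimated correlation, with Irf7 at 1.84 ± 0.29. Hypoxia genes were higher in 5 of 18, 15 over the list alone, adjusted p = 0.571, with Bnip3 at 4.14 ± 0.79. Hepatocyte genes were higher in 2 of 21, 4 over the list alone, adjusted p = 0.958, with Apob at 6.44 ± 1.28. Notch1 (-0.35 ± 0.37) and Trp53 (-1.05 ± 0.28, adjusted p = 0.0503) were not called. edgeR called 674 genes higher and 234 lower of 18039. The counts were 194 and 86 without LCS1, 231 and 92 without LCS2, 337 and 139 without LCS3, 1144 and 423 without LCS4, and 1261 and 473 without LCS5. Of 27 called genes that were followed, 10 kept their call in all these fits. Xlr3b (adjusted p up to 0.0986) and Kcnh5 (up to 0.0826) lost it in 3 of the 5 and Apoc2 in 2.

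LCS-driven primary tumours (n = 10) were set against PPTR primary tumours (n = 11). Sex markers differ between these groups, and the values below are not adjusted for sex. The biliary keratins Krt19 and Krt7 were higher by 9.34 ± 0.82 and 9.04 ± 0.67, with Krt19 at 888 CPM (SD 530) against 1.33 CPM. Epcam, an epithelial adhesion molecule, was higher by 7.4 ± 0.64 and the mucin Muc1 by 7.44 ± 0.54. The mucosal defence genes Dmbt1 (12.07 ± 1.21, 4730 against 1.15 CPM), Reg3b (11.93 ± 1.26) and Reg1 (11.88 ± 1.0) were higher. Tenascin N (Tnn) had 13.86 ± 1.5 and the chloride channel regulator Clca4 10.88 ± 0.79. Pooled ratios were 9820 for the intestinal transcription factor Cdx2 (1760 to 388000), 13800 for Serpinb11 (2480 to 545000), 4580 for Tspan1 (1570 to 22200) and 10800 for Sprr2a2 (3000 to 89500). Sprr2a3, a related cornified envelope gene, had 11.86 ± 0.77. Lower in LCS-driven tumours were the lipid genes Pnpla5 (-9.48 ± 0.88), Mogat1 (-8.67 ± 0.62) and Fitm1 (-7.0 ± 0.81), the adipokine Serpina12 (-7.27 ± 0.51), the cytochrome Cyp4a12a (-9.02 ± 0.84), Sult4a1 (-7.39 ± 0.79), Rims4 (-6.77 ± 0.72) and Mup20 (-6.37 ± 0.8). H19 (-6.73 ± 1.38) and Igf2 (-6.47 ± 1.88) were lower by edgeR, but Igf2 had 0.21 by DESeq2. PPTR tumour 3 had 1260 CPM of Igf2, with at most 3.18 CPM in the other PPTR tumours and a mean of 1.87 CPM (SD 2.42) in LCS-driven tumours, and it also had the highest H19.

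Biliary genes were higher in 11 of 16 and intestinal genes in 6 of 8 with 2 lower, adjusted p = 0.472 for each with an estimated correlation. Fibroblast genes were higher in 14 and lower in 1 of 16, matrix protease genes higher in 14 of 16 and mesenchymal genes in 10 of 15 with 1 lower, adjusted p = 0.472 for each. Col1a1 had 6.14 ± 0.78, with 33600 CPM in tumour 10 and at most 7520 CPM in the others. The protease Mmp7 had 6.49 ± 0.89, Vim 2.14 ± 0.35 and the hypoxia enzyme Car9 6.74 ± 0.46. Proliferation genes were higher in 21 of 24, 22 over the list alone, with the topoisomerase Top2a at 1.96 ± 0.4, adjusted p = 0.54 for the list. Fatty acid synthesis genes were lower in 14 of 15 and bile acid genes in 13 of 14, adjusted p = 0.472 for each. Scd1 had 462 against 24100 CPM (-5.7 ± 0.71) and the bile salt pump Abcb11 -3.17 ± 0.55. Cholesterol synthesis genes were lower in 15 of 21, 16 over the list alone, with 1 higher, adjusted p = 0.588. Hepatocyte genes were lower in 15 of 22 and erythroid genes in 7 of 7, adjusted p = 0.54 for each, and mitochondrial genes in 9 of 9, adjusted p = 0.472. Transthyretin (Ttr) had -3.12 ± 0.4, the cholesterol regulator Insig1 -2.17 ± 0.3 and the heme enzyme Alas2 -3.11 ± 0.31. Trp53 was higher (0.86 ± 0.21), and Notch1 (-0.23 ± 0.19) and Prom1 (-1.21 ± 0.68) were not called. edgeR called 4654 genes higher and 4555 lower of 15926.

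LCS-driven lung metastases (n = 5) carried genes of lung epithelium that were near 0 in LCS-driven primary tumours (n = 10). The club cell protein Scgb1a1 rose by 15.14 ± 0.73 to 552 CPM (SD 383). The surfactant genes Sftpc (13.69 ± 0.81), Sftpb (12.77 ± 0.7) and Sftpa1 (10.02 ± 0.66) rose, with the lung chemokine Cxcl15 (11.75 ± 0.55), Lamp3 (10.71 ± 0.62), Sec14l3 (11.3 ± 0.63) and the sodium channel subunit Scnn1g (8.85 ± 0.52). The tight junction protein Cldn18 rose from 0.0669 to 71.5 CPM (SD 14.3). Scgb3a2 was at least 2140-fold higher. Of 13 lung genes 11 rose, also over the list alone, and the list was called with an estimated correlation (adjusted p = 0.000461). Serpina3k, a serum protease inhibitor, fell from 1720 to 0.47 CPM (-11.78 ± 1.6). Cyp3a11 (-11.89 ± 1.46), Cyp2c39 (-11.37 ± 1.2), the apolipoprotein Apoa5 (-11.3 ± 1.31), Pck1 (-10.94 ± 1.41) and the tyrosine enzyme Hpd (-10.96 ± 1.52) fell, as did Mup10 (-11.85 ± 2.57) and Cyp2c50 (-11.4 ± 1.38). Ratios were 3940 for Mup19 (1090 to 32500) and 1960 for Cyp2c37 (672 to 9530), both higher in primary tumours.

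Hepatocyte genes fell in 16 of 22, 17 over the list alone, adjusted p = 0.204 with an estimated correlation, and bile acid genes in 11 of 14, 12 over the list alone, adjusted p = 0.249. The Kupffer cell gene Clec4f had -10.12 ± 1.12 and the endothelial receptor Stab2 -4.55 ± 0.73. Fibroblast genes fell in 6 of 16, 11 over the list alone, adjusted p = 0.283, with decorin (Dcn) at -2.85 ± 0.68 and Col3a1 at -2.72 ± 0.6. B cell genes rose in 8 of 10, adjusted p = 0.249, with Cd22 up 1.48 ± 0.34. Among them the joining chain Igj had 2.69 ± 0.88, and -0.23 within identifier block 044. Lysozyme (Lyz2) rose by 1.64 ± 0.33 and the neutrophil receptor Csf3r by 2.01 ± 0.39. Hypoxia genes fell in 5 of 18, 6 over the list alone, adjusted p = 0.815, with Bnip3 at -2.01 ± 0.5. The lectin Reg3g rose by 2.56 ± 0.68. No proliferation gene of 24 was called (adjusted p = 0.817 for the list), where the whole table had 5993 genes at an unadjusted p under 0.05 and DESeq2 called 1947 genes higher and 2086 lower. Notch1 (0.16 ± 0.18), Prom1 (0.16 ± 0.41) and Trp53 (0.29 ± 0.22) were not called.

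edgeR called 1652 genes higher and 1525 lower of 18454. Lung metastases 1 and 2, both of block 018, match closely, with an SD of log2 ratios of 0.23 against 0.53 to 1.07 for the other pairs. They were counted as separate here, so p-values may be too small. The counts without lung metastasis 1, 2, 3 or 5 were 1019 and 830, 962 and 767, 1296 and 1017, and 1078 and 1068, in that order. Within identifier block 044 alone, with 3 metastases and 3 primary tumours, they were 17 and 8.

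Peritoneal metastases of the LCS-driven tumours (n = 3) had less RNA of single liver genes. Cyp2a12 was at least 1470-fold and the complement gene C8b at least 976-fold lower than in primary tumours (n = 10). Cyp3a11 had 0.147 against 715 CPM (-11.74 ± 1.91). Lower bounds were 338-fold for Cyp4a14, 369-fold for Ces3b and 346-fold for Sult2a2. Primary tumours exceeded metastases by ratios of 5600 for Apoa5 (1910 to 27100), 3340 for Cyp2c54 (599 to 132000), 3400 for Cyp2c37 (611 to 134000) and 2960 for Mup3 (532 to 117000). Adipsin (Cfd), made by fat cells, rose by 6.85 ± 0.85 from 0.077 to 10.1 CPM. The protease Mmp9 rose by 2.23 ± 0.39, the peptide precursor Penk by 3.58 ± 0.78, Galntl2 by 2.99 ± 0.69, the leukocyte protein Lsp1 by 1.09 ± 0.23 and the transcription factor Foxp1 by 0.73 ± 0.17. The ribosomal-repeat feature AY036118 (8.74 ± 1.76) was at 347000 CPM in metastasis 1 and at most 87.9 CPM in the others, and had -2.37 without metastasis 1. S100a8 (3.29 ± 0.7), S100a9 (2.95 ± 0.62) and mt-Rnr1 (3.2 ± 0.69) lost their call without it, with adjusted p of 0.811, 0.78 and 0.998.

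Hepatocyte genes fell in 6 of 22, 18 over the list alone, adjusted p = 0.0803 with an estimated correlation, and bile acid genes in 7 of 14, 11 over the list alone, also 0.0803. B cell genes rose in 4 of 10, 6 over the list alone, adjusted p = 0.109. Neutrophil genes rose in 2 of 12, 10 over the list alone, adjusted p = 0.252, and adipocyte genes in 2 of 8, 3 over the list alone, adjusted p = 0.0803. No lung gene of 13 was called, adjusted p = 0.934. Stab2 (-6.78 ± 1.11) and the stellate cell gene Reln (-4.5 ± 0.75) fell. Notch1 (-0.03 ± 0.21), Prom1 (-0.68 ± 0.53) and Trp53 (0.11 ± 0.27) were not called. edgeR called 47 genes higher and 185 lower of 18454, and 0 in identifier block 044 alone, where 638 had an unadjusted p under 0.05. DESeq2 called 107 and 551 over all blocks. The edgeR counts were 35 and 85 without metastasis 1, 60 and 23 without metastasis 2, and 6 and 0 without metastasis 3, and only Cfd of 33 called genes that were followed kept its call in all these fits.

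The sites of LCS-driven metastasis were then compared directly, lung (n = 5) against peritoneum (n = 3). Lung genes separated them, 10 of 13 higher in lung also over the list alone, adjusted p = 6.42e-05 with an estimated correlation. Sftpc was at least 21600-fold, Scgb1a1 at least 19300-fold and Sec14l3 at least 2200-fold higher in lung metastases. The ratio was 36400 for Sftpa1 (6540 to 1440000) and 22100 for Sftpb (3970 to 873000). Lower in lung were Cfd (-5.55 ± 1.03), Penk (-6.13 ± 1.09), the neutrophil genes Camp (-6.06 ± 1.28) and Ctsg (-6.74 ± 1.66) and the collagen Col6a5 (-4.09 ± 0.98). Of 8 fits that left out 1 metastasis, Ctsg and Col6a5 lost their call in 6, Camp in 5 and Cfd and Penk in 1 each. Without peritoneal metastasis 1 the adjusted p was 0.3 for Ctsg, 0.0947 for Camp and 0.387 for Col6a5, the highest for each. Neutrophil genes were lower in 1 of 12, 4 over the list alone. Notch1 (0.19 ± 0.24), Prom1 (0.84 ± 0.58) and Trp53 (0.17 ± 0.3) were not called. edgeR called 216 genes higher and 80 lower. The counts were 61 and 44 without peritoneal metastasis 2, 62 and 22 without peritoneal metastasis 3, 135 and 29 without lung metastasis 2, 118 and 27 without lung metastasis 5 and 19 and 0 in block 044. They were 156 and 38 without lung metastasis 1, 184 and 36 without lung metastasis 3 and 261 and 136 without lung metastasis 4.

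PPTR metastases (n = 5, with 2 from intestine and 1 each from lung, peritoneum and liver) were set against PPTR primary tumours (n = 11). The lectin Reg3g rose by 11.97 ± 0.84 from 0.445 to 1620 CPM (SD 571) and Reg3b by 11.41 ± 0.98. The peptide hormone Grp rose by 11.81 ± 0.8, and Gp2, a glycoprotein of pancreas and gut, by 11.04 ± 1.3. The homeobox gene Dbx2 was at least 1730-fold higher. Epcam rose by 5.98 ± 0.66 to 206 CPM and the protease Mmp7 by 6.92 ± 0.98 to 285 CPM. Krt19 rose by 4.51 ± 0.89, with 174 CPM in the lung metastasis and at most 16.6 CPM in the others. Mannose-binding lectin 2 (Mbl2) fell by 8.12 ± 0.64 from 242 to 0.862 CPM. Clec4f (-9.03 ± 1.58), the cytochromes Cyp1a2 (-7.56 ± 1.02) and Cyp2b9 (-8.38 ± 1.61) and Sult4a1 (-8.12 ± 1.23) fell as well.

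Biliary genes rose in 9 of 15, 10 over the list alone, and proliferation genes in 9 of 24, 11 over the list alone, adjusted p = 0.51 and 0.532 with an estimated correlation. The mitotic kinase Bub1b rose by 1.66 ± 0.42, Cd44 by 2.09 ± 0.25 and Vim by 2.25 ± 0.44. Matrix protease genes rose in 5 of 16, 8 over the list alone, adjusted p = 0.51. Fatty acid synthesis genes fell in 13 of 15, 14 over the list alone, and bile acid genes in 12 of 14, 13 over the list alone, adjusted p = 0.417 for each. The elongase Elovl6 (-4.52 ± 0.83), Slc10a1 (-5.41 ± 0.83) and the phospholipid exporter Abcb4 (-3.88 ± 0.44) fell. Cholesterol synthesis genes fell in 14 of 21, 16 over the list alone, with 1 higher, and Hmgcs1 fell by 1.99 ± 0.43. Hepatocyte genes fell in 8 of 22, adjusted p = 0.51 for both lists. Lung genes rose in 6 of 7, adjusted p = 0.51. The surfactant gene Sftpd had 3.51 ± 0.9 and Sftpa1 6.72 ± 1.16, and the lung metastasis had 204 and 487 CPM of them against at most 5.12 and 3.44 in the others. Without it Sftpd had -0.08 and Sftpa1 an adjusted p of 0.0653. Notch1 (-1.15 ± 0.3) and Trp53 (-1.02 ± 0.25) fell, and Prom1 was not called (-1.42 ± 1.2). edgeR called 2637 genes higher and 2786 lower of 16246.

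HBS1_F2-driven peritoneal metastases (n = 3) against HBS1_F2-driven primary tumours (n = 2) gave 0 genes called by edgeR of 16362, with 887 at an unadjusted p under 0.05. DESeq2 called 70 higher and 16 lower, and edgeR 21 and 14 without metastasis 3, whose deposited identifier carries the sample-type code usual for primary tumours. Over the list alone 6 of 7 mesothelial genes were higher, adjusted p = 0.758 with an estimated correlation, as were 1 p53 target of 18 and 1 matrix protease gene of 16. Notch1 (0.35 ± 0.38), Prom1 (0.4 ± 0.31) and Trp53 (0.23 ± 0.34) were not called.

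HBS1_F2 organoids (n = 4) were set against HBS1 organoids (n = 4). No identifier block holds libraries of both, so block and group cannot be told apart. By the labels each group is a single line. The p-values cover the spread between the libraries of each name, also those that stood apart, and not between lines. In each group 1 library stood apart. HBS1 library 3 had Ddx3y at 157 CPM and Xist at 0.142, where the other 3 had at most 0.0345 and 1210 to 2260. HBS1_F2 library 2 had Alb at 1.31 CPM and RNaseP_nuc at 866, where the other 3 had 230 to 983 and 4.61 to 38.0. Epcam fell by 6.94 ± 1.25 from 510 to 4.12 CPM, and Krt7 (-5.78 ± 1.01) and the tight junction protein Cldn4 (-5.17 ± 0.85) fell too. Vim rose by 6.65 ± 0.69 from 2.3 to 232 CPM, the transcription factor Zeb1 by 3.76 ± 0.32 and Sparc by 10.23 ± 0.94. Alb rose by 9.02 ± 1.73 and Apob by 7.56 ± 1.26. Vitronectin (Vtn), a liver plasma protein, rose by 13.39 ± 2.66 to 1590 CPM (SD 1130), angiotensinogen (Agt) by 10.21 ± 2.03, the growth factor receptor Pdgfra by 9.62 ± 1.88 and the collagen Col3a1 by 10.71 ± 2.98. Mmp7 (-8.55 ± 1.15), the potassium channel subunit Kcne3 (-9.8 ± 1.06), the nucleoside transporter Slc28a3 (-8.27 ± 0.58) and the zinc finger gene Zfp711 (-8.16 ± 0.9) fell. Nptx2 was 3720 times higher in HBS1 organoids (668 to 147000). Notch1 rose by 2.31 ± 0.63 to 562 CPM (SD 328), adjusted p = 0.0422, and was called in 1 of 8 fits that left out 1 library. Of 55 called genes that were followed, 24 kept their call in all 8 fits. Col3a1 lost it in 6 (adjusted p up to 0.107), Pdgfra in 3, Agt in 2 and Vtn in 1. Prom1 (-2.45 ± 1.09) and Trp53 (0.08 ± 0.35) were not called.

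Biliary genes fell in 7 of 16, 8 over the list alone with 1 higher, and mesenchymal genes rose in 6 and fell in 1 of 15, or 8 and 2 over the list alone, adjusted p = 0.646 for each with an estimated correlation. Hepatocyte genes rose in 4 of 9, 7 over the list alone, adjusted p = 0.701. Interferon genes rose in 4 of 12, 6 over the list alone, adjusted p = 0.646, with Ifit1 up 3.75 ± 0.53. edgeR called 1482 genes higher and 1031 lower of 15601. Without HBS1_F2 library 2 the counts were 3634 and 2986, and without any other single library they were 488 to 872 and 485 to 681. The lowest came without HBS1 library 4, and without HBS1 library 3 they were 535 and 522.

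Normal liver organoids (n = 6) had less RNA of all listed liver genes than normal liver (n = 6). Hepatocyte genes fell in 22 of 22 and bile acid genes in 14 of 14, adjusted p = 0.189 and 0.11 with an estimated correlation. Cyp2e1 fell by 14.25 ± 1.17 from 4570 to 0.235 CPM, and the tryptophan enzyme Tdo2 had -14.01 ± 0.88. Mup7 was at least 24100-fold lower, and liver exceeded organoids by ratios of 155000 for Mup1 (42800 to 1280000), 134000 for Mup2 (37100 to 1110000), 116000 for Mup3 (39700 to 562000) and 184000 for Mup8 (33100 to 7280000). Biliary genes rose in 16 of 16, adjusted p = 0.189. Cldn4 rose by 12.66 ± 0.77 to 984 CPM (SD 425) and Krt7 by 9.15 ± 0.66. The prostaglandin synthase Ptgs2 rose by 11.82 ± 0.83. Spink4 was at least 1720-fold, the transcription factor Pax9 at least 1220-fold and the chemokine Cxcl3 at least 849-fold higher.

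Endothelial genes fell in 14 of 14 (adjusted p = 0.0612), fibroblast genes in 15 of 15 and macrophage genes in 14 of 15 with 1 higher. Clec4f was at -13.39 ± 0.89 and Dcn at -11.5 ± 0.75. Immediate early genes rose in 10 of 11, p53 targets in 16 of 18 with 1 lower and proliferation genes in 13 of 24. Interferon genes fell in 12 of 13. The adjusted p of these lists was 0.189 to 0.635 with an estimated correlation. Prom1 rose by 5.5 ± 1.01 to 340 CPM and Trp53 by 2.17 ± 0.3, and Notch1 was not called (0.4 ± 0.26). edgeR called 5775 genes higher and 5440 lower of 15000. Ribosomal-repeat shares of 0.256% to 0.72% in organoids and 10.7% to 25.8% in livers do not overlap, and neither do reads not aligned, at 1.88% to 6.77% and 20.2% to 42.8%, and with the share as a covariate 115 genes were higher and 486 lower. The 8 PPTR tumours with shares of 0.21% to 0.503% had Alb at 28000 to 90900 CPM and Krt19 at up to 6.46 CPM, against at most 27.6 and 402 to 857 CPM in organoids, so a low share alone does not bring these levels.

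The difference between LCS and normal organoids was tested against the difference between PPTR primary tumours and normal liver. The acute phase protein Orm3 (13.95 ± 2.22), RNaseP_nuc (11.32 ± 1.15) and Mettl7b (10.61 ± 1.24) had the more positive change in organoids. RNaseP_nuc was at 20 CPM or more in 19 of 19 LCS and 0 of 6 normal organoid libraries, but in 11 of 11 PPTR tumours and 5 of 6 normal livers. This split of the libraries enters the tested difference and cannot be told apart from it. Tmc5 (-12.28 ± 1.24), Stc1 (-11.07 ± 2.69) and Slc9a4 (-9.51 ± 1.41) had the more positive change in tumours. Fitted values of Orm3, with 1 count over all normal organoids, and of Tmc5, Stc1 and Slc9a4, with 1, 0 and 2 counts over all normal livers, are neither exact nor bounds. Hepatocyte genes were higher in this difference in 14 of 22, 21 over the list alone, and bile acid genes in 10 of 14, 13 over the list alone, adjusted p = 0.329 for each with an estimated correlation. Fgb had 9.82 ± 1.54, Apob 7.12 ± 1.19, Ly6d -7.92 ± 1.25, Scd2 -4.57 ± 0.73 and the lactate enzyme Ldha 1.96 ± 0.44. Prom1 was called (-4.52 ± 1.53, adjusted p = 0.0391). It lost its call in 5 of 6 fits that left out 1 LCS line or normal liver 6 (adjusted p up to 0.0677, without LCS1). Notch1 (-0.02 ± 0.4) and Trp53 (-0.47 ± 0.4) were not called. edgeR called 1945 genes higher and 1233 lower of 17488, so that 61% of the calls were higher. With DESeq2 size factors, which moved the median of all genes by -0.1, the counts were 1619 and 1484, or 52.2% higher.

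**Figure D3:**
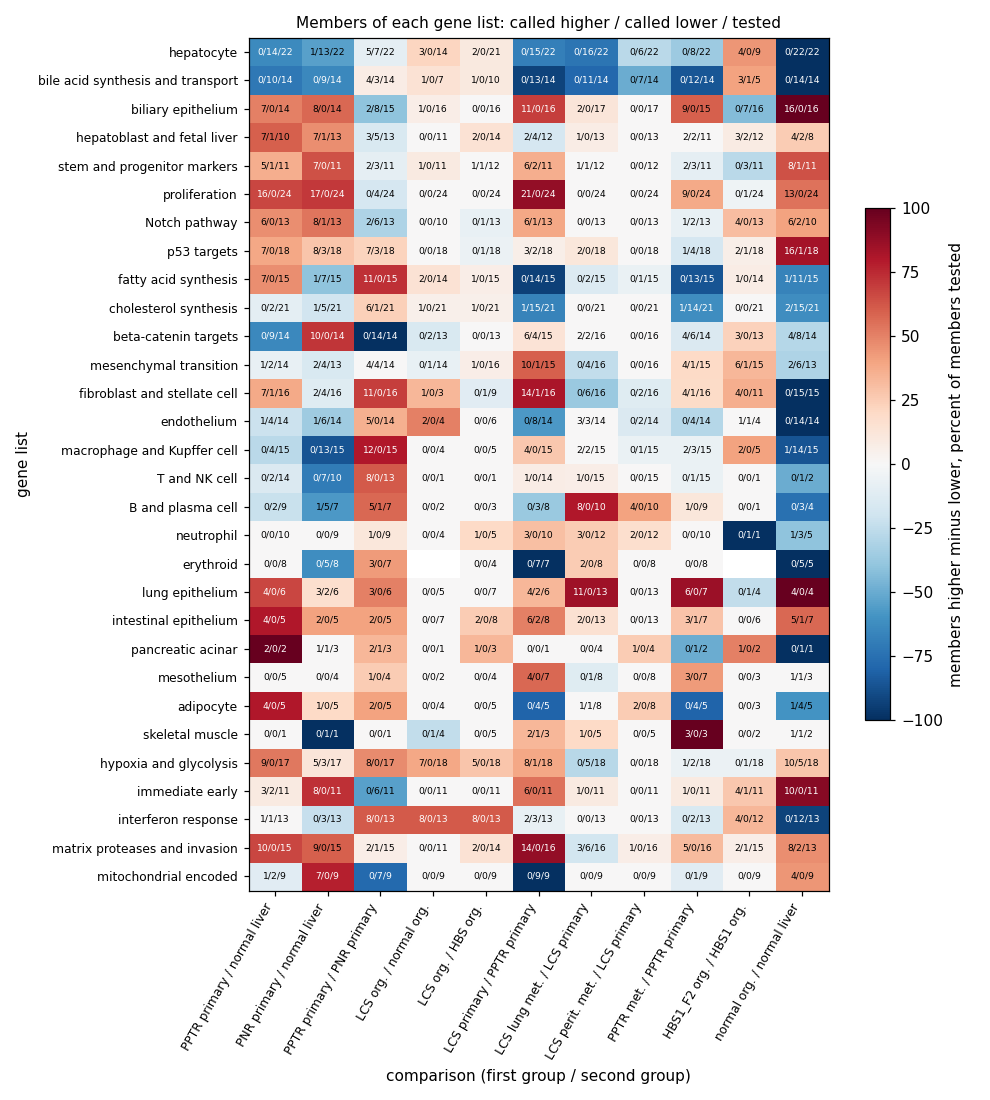
Members of each gene list (vertical axis) called higher, called lower and tested in 11 comparisons (horizontal axis), as numbers in the cells, with color for members higher minus lower in percent of members tested (red positive, blue negative). Hepatocyte genes are lower in 22 of 22 in normal organoids against normal liver, and lung genes higher in 11 of 13 in LCS-driven lung metastases against primary tumours.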

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

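The tests of the RNaseP_nuc pattern, of blocks and of lung tissue in the metastases and of the ribosomal-repeat share, and the look at sex markers and identifier codes, were chosen only after the result was seen.

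RNaseP_nuc, AC120136.3 and the pseudogene Rpl34-ps1 split the libraries across groups. Rpl34-ps1 took at most 8.7% of its sum with Rpl34 in normal organoids and at least 71.7% in LCS organoids, and normal liver 6 had 0.068 CPM of RNaseP_nuc against 176 to 354 CPM in the other livers. A difference between identifier blocks is argued against, since 5 of 9 blocks hold libraries of both RNaseP_nuc levels. Another aligner as the whole cause is argued against only for the 9 libraries that lie between the limits, all named HBS1 or HBS1_F2. No library of another name lies between, so for the others another aligner stays open. A strain or donor variant against the reference may be the cause, since 7 of 7 tumours grown under the names HBS1 and HBS1_F2 lie between, as a mix of RNA from organoid cells and another animal could. That mix leaves the cultures unexplained, since the 4 HBS1_F2 organoid libraries had shares of 8.11%, 11.1%, 19.3% and 84.8% and the 2 in the middle also lie between. What stays open is why PNR tumours 4 to 6 (237 to 300 CPM) and HBS1 organoid 3 (348 CPM against 0.418 to 1.03 in the others) had high RNaseP_nuc at a low Rpl34-ps1 share. HBS1 organoid 3 had 157 CPM of Ddx3y and 0.142 of Xist, against at most 0.0345 of Ddx3y and 1210 to 2260 of Xist in the other 3 libraries of its line. PNR tumours 4 to 6 also had Ddx3y (46.9 to 61.4 CPM) and little Xist (0.652 to 0.747), with Prom1 at 0.313 to 0.417 CPM. The sex markers of HBS1 organoid 3 argue against a shared animal of origin with the other 3 libraries of its line. It was kept in the sum of that line. Whether its label or that of another library is wrong was not tested, and strain was not tested as a biological difference between LCS and normal organoids.

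Genes of liver and lung differed between LCS-driven metastases and primary tumours. Liver tissue in the primary tumour libraries is a candidate explanation, since hepatocyte genes and the liver macrophage genes Clec4f, Timd4 and Vsig4 varied together over the 10 primary tumours, the only relation computed, with Spearman rho 0.84 (permutation p = 0.00368), Pearson r 0.9 (permutation p = 0.00188) and r 0.67 without the 2 tumours farthest from the median. Within block 016 (n = 7) r was 0.77 (exact permutation p = 0.0512) and rho 0.82 (exact permutation p = 0.0341), two-sided throughout, and block 044 holds 3 primary tumours. Timd4 and Vsig4 were not confined to primary tumours, since they reached 6.83 and 3.56 CPM in metastases, inside their ranges of 0.407 to 9.59 and 0.657 to 59.7 in primary tumours, while Clec4f was at most 0.0655 CPM in metastases. A difference between blocks as the whole cause is argued against by a median hepatocyte difference of -3.76 log2 (SD 2.1 over the 22 genes) within block 044, against -4.87 over all blocks. That SD gives no spread between the 6 metastases and 3 primary tumours of the block. With libraries as replicates, edgeR called few genes in this block for lung metastases and no gene for peritoneal ones. Lung tissue in the lung metastases and expression of lung genes by tumour cells cannot be told apart, since the 11 of 13 lung genes above every primary tumour in all 5 lung metastases restate the difference itself (Sftpc at 353 CPM or more against at most 0.319, Scgb1a1 at 123 or more against at most 0.0532). A biological change of the tumour cells at each site stays open and untested.

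Genes called against normal liver coincide with a high ribosomal-repeat share in that tissue. For PPTR tumours the share as the whole cause is weakly argued against, since 2043 of 5047 genes were called with and without it as a covariate. That fit rests on few tumours, since 8 of the 11 had shares of 0.21% to 0.503% and only the others come nearer to liver, up to 18.3%. For normal organoids and PNR tumours the covariate decides nothing, since their shares of 0.256% to 0.72% and 0.925% to 2.12% do not meet those of liver, 10.7% to 25.8%, and the median standard error rose from 0.28 to 1.54 and from 0.26 to 1.27. They were set instead against the 8 PPTR tumours with shares of 0.21% to 0.503%. For normal organoids the share as the whole cause is argued against, since in 6616 of the 11215 called genes all 8 tumours lay on the liver side of every organoid library, where chance gives about 3.73, and in 23 on the far side. Alb was at 28000 to 90900 CPM in these tumours and at most 27.6 in organoids. For PNR tumours it is argued against for 1175 of 7758 called genes in the same sense. Chance gives about 0.319 if all PNR libraries are separate, and more if the closely matching ones are not. Among the 1175 is Igf2, at most 3.18 CPM in the 8 tumours and at least 679 in PNR tumours. In 33 genes the tumours lay on the far side. These 1175 are 15.1% of the calls, under the bound used, and for the other genes share and group cannot be told apart. A biological difference of tumours or organoids from liver stays open.

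A library was far from the rest of its group in 13 of 96 sets of values, where chance gives about 1 in 20. HBS1_F2 organoid 2 had 79.4 CPM of Notch1 against 657 to 790 CPM in the others. HBS1 organoid 3 had 5.03 CPM of Prom1 against 280 to 472. LCS-driven lung metastasis 4 had 718 CPM of Krt19 against 1740 to 2380. LCS3 organoid 1 had a ribosomal-repeat share of 6.66% against 0.523% to 1.46%. LCS5 organoid 3 had 29.4 CPM of Trp53 against 36.2 to 37.4. LCS-driven primary tumour 4 had a ribosomal-repeat share of 6.3% against 0.159% to 2.44%. PNR tumour 7 had 15.2 M gene counts against 33.9 M to 48.5 M, and PNR tumour 8 had 3570 CPM of Alb against 7670 to 11100. PPTR intestine metastasis 1 had a ribosomal-repeat share of 8.2% against 0.174% to 0.844%. Normal liver 6 had 29.4 M gene counts against 9.48 M to 16.7 M. Normal organoid 6 had 22.6 CPM of Trp53 against 37.1 to 49.6.

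The deposited identifiers carry a sample-type code, and 9 libraries have another code than usual in their group. They are PPTR primary tumours 10 and 11, which have the code usual for metastases, and LCS-driven lung metastasis 5, the PPTR intrahepatic metastasis and HBS1_F2-driven metastasis 3, which have the one usual for primary tumours. The others are LCS1 organoid 1, LCS2 organoid 1, normal liver 6 and normal organoid 3. The labels were followed.

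The change from normal to LCS organoids differed from the change from normal liver to PPTR tumours in 3178 genes by a test of the difference itself. Among genes under the naming rule, the largest fitted values were those of Orm3 (13.95), RNaseP_nuc (11.32) and Mettl7b (10.61) in one direction and Tmc5 (-12.28), Stc1 (-11.07) and Slc9a4 (-9.51) in the other. Orm3, Tmc5, Stc1 and Slc9a4 had at most 2 counts in all libraries of a group, so their size and order are not fixed by the data.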

How the results depend on the processing

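The tests with the ribosomal-repeat share, sex, protein-coding features, HBS1 organoid 3, normal liver 6, PNR tumours 4 to 6 or closely matching libraries were chosen only after the result was seen. No paired analysis was possible because the labels give no replicate number that links libraries across groups. Over all settings, named genes kept direction and side of the threshold in 7389 cases, lost the call in 872, gained one in 11, moved in 32 and reversed in 7. With sex as a covariate, fitted in some tumour comparisons only, they kept both in 401 cases, lost the call in 26 and moved in 1. Counts stayed within 1.5 times in every setting run for LCS-driven against PPTR primary tumours, PPTR metastases against primary tumours and the difference between comparisons, and for normal organoids against liver in every setting but the ribosomal-repeat share. The preset correlation called lists in 147 cases where the estimated one did not. In simulated data with 5 lines against 6 libraries the test called 16% of 2-fold changes. Depth was not varied, so what it limits was not tested. Where no construction is named below, the cause was not tested.

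With the ribosomal-repeat share as a covariate, 1560 genes were higher and 1101 lower in PPTR tumours against liver and mt-Nd1 had -0.03. In PNR tumours against liver 1 was higher and 1 lower, and in normal organoids against liver 115 and 486. Without the filter 7105 genes were lower in PPTR against PNR tumours, and HBS organoids had 87 higher and 68 lower than normal organoids. The DESeq2 test gave 1399 and 994 for LCS against normal organoids, 254 and 256 for HBS against normal organoids, 1449 and 720 for LCS against HBS organoids, 107 and 551 for peritoneal metastases, 409 and 198 for lung against peritoneal metastases, 70 and 16 for HBS1_F2-driven metastases, and 2816 and 1749 for HBS1_F2 against HBS1 organoids. It turned Peg3 (1.54) and Afp (1.04) in PPTR against PNR tumours and Igf2 (0.21) in LCS-driven against PPTR tumours.

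Every library as a replicate gave 1337 and 1013 for LCS and 195 and 231 for HBS against normal organoids, and 2374 and 1620 for LCS against HBS organoids. Protein-coding features gave 3 higher for HBS against normal organoids, HBS1_F2 as another line 0 and 7, and HBS1 organoid 3 left out 2 higher. Summing the closely matching lung metastases 1 and 2, with fewer samples, gave 992 and 788 against primary tumours and 32 lower against peritoneal metastases.

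Single blocks, with fewer samples, gave 4 and 4 for LCS against normal organoids, 5 and 66 for HBS against normal organoids and 103 and 31 for LCS against HBS organoids in block 045. Block 044 gave 17 and 8 for lung metastases with Igj at -0.23, 0 and 0 for peritoneal metastases by edgeR, where 638 genes had an unadjusted p under 0.05, and 19 and 0 for lung against peritoneum.

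Of the called genes that were followed, those that kept their call whichever replicate was left out were 23 of 38 for LCS against normal organoids, 10 of 27 for LCS against HBS organoids, 49 of 71 for lung metastases, 1 of 33 for peritoneal metastases and 5 of 14 for lung against peritoneal metastases. They were 73 of 91 for PPTR metastases, 24 of 55 for HBS1_F2 against HBS1 organoids and 39 of 51 for the difference between comparisons.

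Leaving out each replicate in turn, with fewer samples, gave 272 to 933 higher and 166 to 539 lower for LCS against normal organoids, with the lowest without LCS2 and the highest without LCS5. LCS against HBS organoids had 194 to 1261 and 86 to 473, lowest without LCS1 and highest without LCS5. Lung metastases had 962 to 1718 and 767 to 1990, lowest without metastasis 2 and highest without metastasis 4. Peritoneal metastases had 6 to 60 and 0 to 85. The 6 and 0 came without metastasis 3. AY036118 kept its call in 1 of the 3 fits and ran from -2.37 without metastasis 1 to 9.32 without metastasis 2. Lung against peritoneal metastases had 61 to 261 and 22 to 136. PPTR metastases had Sftpd at -0.08 without the lung metastasis and at up to 3.82 without another. HBS1_F2-driven metastases had 0 to 21 and 0 to 14, with the highest without metastasis 3. HBS1_F2 against HBS1 organoids had 488 to 3634 and 485 to 2986, lowest without HBS1 organoid 4 and highest without HBS1_F2 organoid 2.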

Other observations

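The groupings of lines and libraries in the first 2 paragraphs were chosen only after the result was seen, whereas the counts of other splits were planned.

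The 5 LCS organoid lines differed among themselves. Vim was at 235 CPM in LCS1, 151 in LCS2 and 82.1 in LCS3, but at 0.503 in LCS4 and 2.01 in LCS5, with 0.673 to 116 CPM in the 6 normal organoids. The intestinal transcription factor Cdx2 was at 55.8, 55.4 and 31.0 CPM in LCS1 to LCS3 and at 8.95 and 5.23 CPM in LCS4 and LCS5. Alb was at 235 CPM in LCS1, 277 in LCS3 and 23.9 in LCS2, and at 1.58 and 2.9 CPM in LCS4 and LCS5. The inflammasome gene Naip1 was at 323 and 329 CPM in LCS1 and LCS2 and at most 10.5 CPM in the others. Krt19 ran from 287 CPM in LCS4 to 1230 CPM in LCS1, and Prom1 from 3.36 CPM in LCS1 to 112 CPM in LCS4. Each value is the sum of a line's libraries, and no test was made between single lines. All libraries of LCS1 and LCS2 are in identifier block 016, those of LCS3 and LCS4 in block 045 and those of LCS5 in block 047. Line and block therefore cannot be told apart between these blocks, as for Naip1. LCS3 and LCS4 share a block and still differed in Vim, Cdx2 and Alb. Over the 19 single libraries Alb ran from 0.454 to 597 CPM, Krt19 from 221 to 2710 CPM and Prom1 from 2.37 to 228 CPM. Libraries of a line thus differ too, and a sum can rest on 1 of them.

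Cultures and tumours labelled HBS1 or HBS1_F2 had the following levels of liver, fetal and biliary genes, and how they descend from each other is not given in the sources used here. In the 4 HBS1 organoid libraries Krt19 was at 188 to 590 CPM, Alb at 0.207 to 1.38 CPM, H19 at 0.069 to 0.831 CPM and Igf2 at 0.966 to 3.95 CPM. The 2 HBS1-driven primary tumours had Alb at 15600 and 28300 CPM, Afp at 209 and 1520 CPM, H19 at 1300 and 2870 CPM, Igf2 at 1420 and 3260 CPM and Krt19 at 0.226 and 0.362 CPM. The 2 HBS1_F2-driven primary tumours had Alb at 4660 and 4740 CPM, and the 3 HBS1_F2-driven metastases Alb at 1300 to 4110 CPM, Igf2 at 1060 to 6780 CPM and Krt19 at 0.701 to 16.7 CPM. The 4 HBS1_F2 organoid libraries had Krt19 at 0.676 to 56.3 CPM, Vim at 105 to 494 CPM and Alb at 1.31 to 983 CPM.

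Other splits of the same libraries into groups of the same sizes were tested for 14 comparisons. In 13 of them the real split called the most genes. As large were 1 of 100 splits, 1 of 56 for lung against peritoneal metastases and 1 of 35 for HBS1_F2 against HBS1 organoids. In the last, each group is a single line by its labels and only the spread between its libraries is covered. Each share is under 0.05, which argues against chance for a comparison taken alone, without adjustment over the 14 tests. Closely matching PNR or lung metastasis libraries were moved as separate ones, so shares of their comparisons may be too small. Splits for the difference between comparisons also undo both differences themselves, so they cannot decide whether these are equal. For peritoneal metastases 4 of 100 splits, the real one included, called as many as the real 232 genes. This share is close to the limit and not adjusted over the 14 tests. The highest other split called 416 and put peritoneal metastases 2 and 3 with primary tumour 10, all 3 of block 044. Within that block edgeR called 0 genes between metastases and primary tumours, with 638 at an unadjusted p under 0.05, and DESeq2 was run over all blocks only, with 107 and 551. The highest other split called 4 genes for PPTR tumours against liver (5047 in the real one), 2846 for PNR tumours against liver (7758) and 734 for PPTR against PNR tumours (8170). It called 121 for LCS (933) and 3 for HBS (12) against normal organoids, 680 for LCS against HBS organoids (908), 5824 for LCS-driven against PPTR tumours (9209) and 470 for lung metastases (3177). For lung against peritoneal metastases it called 145 (296), for PPTR metastases 25 (5423), for HBS1_F2 against HBS1 organoids 454 (2513), for normal organoids against liver 6178 (11215) and for the difference between comparisons 1622 (3178). HBS1_F2-driven metastases, 3 against 2, were not tested in this way.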
